A study of Mus musculus with 16 samples.

How the data were processed

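Array comparative genomic hybridisation was used to compare tail DNA of 8 C57BL/6 mice of 1 family with tail DNA of 1 common reference male of the same colony. The method labels the DNA of a mouse and of the reference with different dyes, hybridises both to 1 array, and reads relative copy number from the ratio of the dyes at each probe. The family held a sire, a dam and 6 progeny. Per the series title, males of this family were exposed to gamma rays at 0.05 mGy per day for 400 days, while the design text calls this sire non-irradiated. The labels do not settle which holds, so no result here is read as an effect of radiation. Each mouse was hybridised on 2 arrays with the dyes exchanged, which gave 16 arrays. The 2 arrays of a mouse are a technical repeat and were counted as 1 replicate. Each of sire and dam is therefore 1 sample, and the progeny group has n = 6.

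The deposited scanner files hold intensity values for 973116 spots, of which 966371 are not controls. Per the file headers, the images were read with Agilent Feature Extraction 12.1.0.3 against the mouse build mm9. Its processed signals had been background-subtracted and multiplied by 1 linear dye factor per channel, per the file headers, with no intensity-dependent dye correction. The series' value table holds log2 values deposited by the authors. Set against the scanner values of the same array, each column of it ran as reference over mouse, with correlations with log2 of mouse over reference between -0.9997 and -0.976. Its centring was close to 0 but is not stated, and a further correction in it is unknown. The column medians with the mouse in Cy3 were 0.012 for the sire, 0.013 for the dam, and 0.015, 0.016, 0.017, 0.011, 0.014 and 0.014 for progeny 1 to 6. With the mouse in Cy5 they were -0.0017, -0.0014, -0.0032, 0.0057, -0.0096, -0.0015, 0.017 and 0.011 in the same order of mice.

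From the processed signals, log2 of mouse over reference was computed with the direction taken from the dyes in the labels. Spots with an outlier flag on any array were left out, which removed 4061 spots. Spots of 1 probe were averaged, the autosomal median of each array was set to 0, and no loess was applied. The analysis used 947830 autosomal probes at a median spacing of 2056 bp, most of them 60 bp long. The array also carries 68 probes on X and 23 on Y, which entered no call. Median spot signal ranged from 115 to 347 in the green channel against median backgrounds of 28 to 35, and no spot was saturated. The number of arrays, 2 per mouse, limits the precision. Noise of a mouse was estimated from differences between neighbouring probes of its averaged track and lay between 0.067 and 0.16 on the log2 scale.

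Regions were called with an interval search that scores each run of probes by the sum of its noise-scaled log2 ratios over the square root of the number of probes. A call needed a score of 6, at least 3 probes, an absolute mean of 0.25, and the same sign with a score of at least 3 in each dye orientation. Overlapping calls of 1 sign were merged over mice. A region counted as progeny only when neither parent had an overlapping call of that sign and the progeny differed from each parent by more than all but 10 of 10000 random windows of that length. This comparison of single mice describes these mice and is not a p-value. As a background, the same search was run on the difference of the orientations divided by 2, in which copy number cancels, after the dye effect shared by all mice was removed. The main calls kept this dye effect in their orientation rule, so the background is set beside calls with it removed as well. For tests across mice, the probes were averaged into 94774 windows of 10 neighbouring probes and fitted with limma 3.58.1 in R 4.3.3. Groups were sire, dam and progeny, and p-values were two-sided with Benjamini-Hochberg adjustment at 0.05. The spread comes from the 6 progeny, and each single parent is assumed to vary like them. The ratio against 0 leaves out the spread between reference mice, since there is 1. Calls per mouse were compared by an exact permutation test. Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3 were used.

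The search was tested on simulated tracks with the noise and shared dye effect of each mouse. With planted changes of 0.585 on the log2 scale, it recovered 81.9 percent of segments of 3 probes, 98.1 percent of those of 5 probes and 100.0 percent of those of 10 probes, and it made 0 false calls. These shares are pooled over mice of unlike noise. The simulated noise was normally distributed and independent between probes, which the measured tracks need not be. The 0 false calls therefore do not carry over to the measured tracks. There the background search made 12 to 91 calls in the progeny, and 136 of the 273 called regions had 1 probe past 0.3 in the mouse with the largest mean. In the simulated fit of progeny against the reference, 92 percent of windows changed by 0.1 and all windows changed by 0.2 or more were recovered, with 2 false calls. In the simulated comparison with the sire, 0 percent of changes of 0.1, 48 percent of changes of 0.2 and 100.0 percent of changes of 0.585 were recovered. The corresponding shares for the dam were 0, 52 and 100.0 percent. In these simulated fits each change was planted in all 6 progeny and over a whole window. The shares therefore do not apply to changes in single progeny or in fewer probes.

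Before the data were examined, these choices were fixed: groups, tests, thresholds, alternatives and the rule for named regions. The rule takes up to 10 regions of each of 4 classes by score. The classes are regions called in all mice, in progeny and neither parent, in a parent and some progeny, and in a parent and no progeny. It also takes the 5 windows with the smallest adjusted p of each limma contrast with a call. The alternatives were normexp background correction with an offset of 50, the series' value table, leaving out dim probes, other thresholds and window sizes, a single dye orientation, subtraction of a running median along each chromosome, and leaving out each of the progeny. The normexp alternative used median spot signals, since the files as read here gave no mean signal. The fixed gene lists and the correction for GC content were not run, because no annotation or genome of build mm9 was used here. Regions are therefore given by position, without genes. Scans fell on 4 days, with sire and dam on day 1, progeny 1 and 2 on day 2, progeny 3 and 4 on day 3, and progeny 5 and 6 on day 4. Sire and dam were compared within 1 day, and scan day was added as a random block after the data were seen.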

Results

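Relative DNA copy number was measured along the 19 autosomes of a sire, a dam and their 6 progeny, each against the same reference male. The design asks whether progeny carry copy number changes that their parents lack. Whole chromosomes stayed near the reference in all 8 mice, with medians of the single autosomes between -0.011 and 0.015 on the log2 scale. The search called 273 regions in at least 1 mouse, 238 of them of 3 or 4 probes and 238 of them in 1 mouse alone. All positions are those of build mm9.

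A block on chromosome 4 was present at a higher copy number than in the reference in all 8 mice, at levels that differed between mice. It ran from 101110482 to 101270535, a length of 160 kb covered by 73 probes. The mean log2 ratio was 0.57 ± 0.0066 (SD between the 2 dye orientations, as for all single mice below) in the sire and 0.95 ± 0.0032 in the dam. Progeny 2, 5 and 6 had means of 0.56 ± 0.04, 0.57 ± 0.02 and 0.56 ± 0.02. Progeny 1, 3 and 4 had means of 0.98 ± 0.04, 0.97 ± 0.02 and 0.95 ± 0.0091. The difference of 0.38 between dam and sire was larger than the 0.038 that random windows of this length reached at the 99th percentile for that pair. For each of the progeny, the difference from 1 parent lay inside the corresponding range and the difference from the other parent outside it. The 40 probes on each side of the block had means between -0.02 and 0.02 in every mouse.

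**Figure D1:**
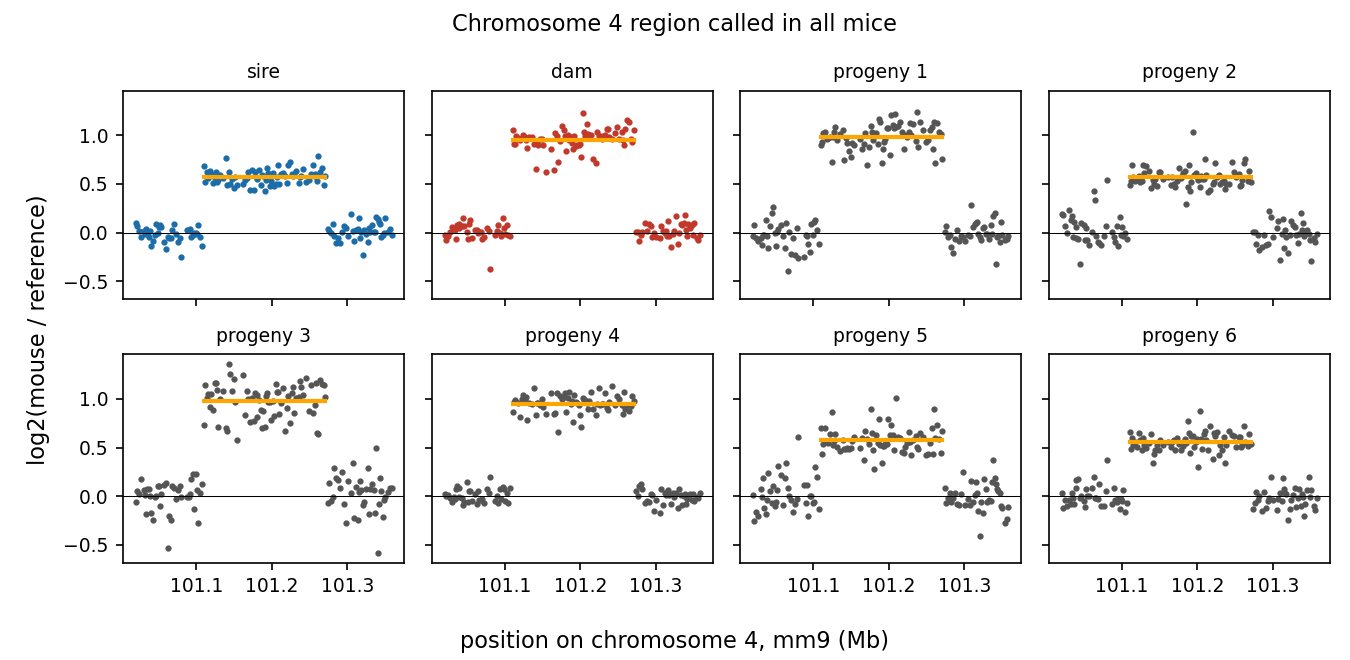
Log2 of mouse over reference (vertical axis) against position on chromosome 4 in Mb (horizontal axis) for each of the 8 mice. Each point is 1 probe, averaged over both dye orientations, with 40 probes on each side of the called region, and the orange line is the region mean. The sire and progeny 2, 5 and 6 sit near 0.57, and the dam and progeny 1, 3 and 4 sit near 0.95 to 0.98.

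A stretch of chromosome 14 was lower than in the reference in all 8 mice. It ran from 53344285 to 54405220, a length of 1061 kb with 120 probes and gaps in coverage. Means were -0.41 ± 0.02 in the sire, -0.45 ± 0.01 in the dam and -0.41 ± 0.029 in the progeny (SD, n = 6), and ranged from -0.45 in progeny 3 to -0.38 in progeny 2. Progeny 2 lay 0.068 above the dam and progeny 1 lay 0.047 above it, past the 0.038 and 0.0435 that random windows reached at the 99th percentile for these pairs. The level changed inside the stretch, from -0.27 between 53397427 and 53447890 to -0.68 between 53673489 and 53961747 as progeny means. The chromosome 14 difference is measured against 1 reference mouse and may belong to that mouse. The number of regions called in all mice was 2 under every alternative of the search that was run.

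**Figure D2:**
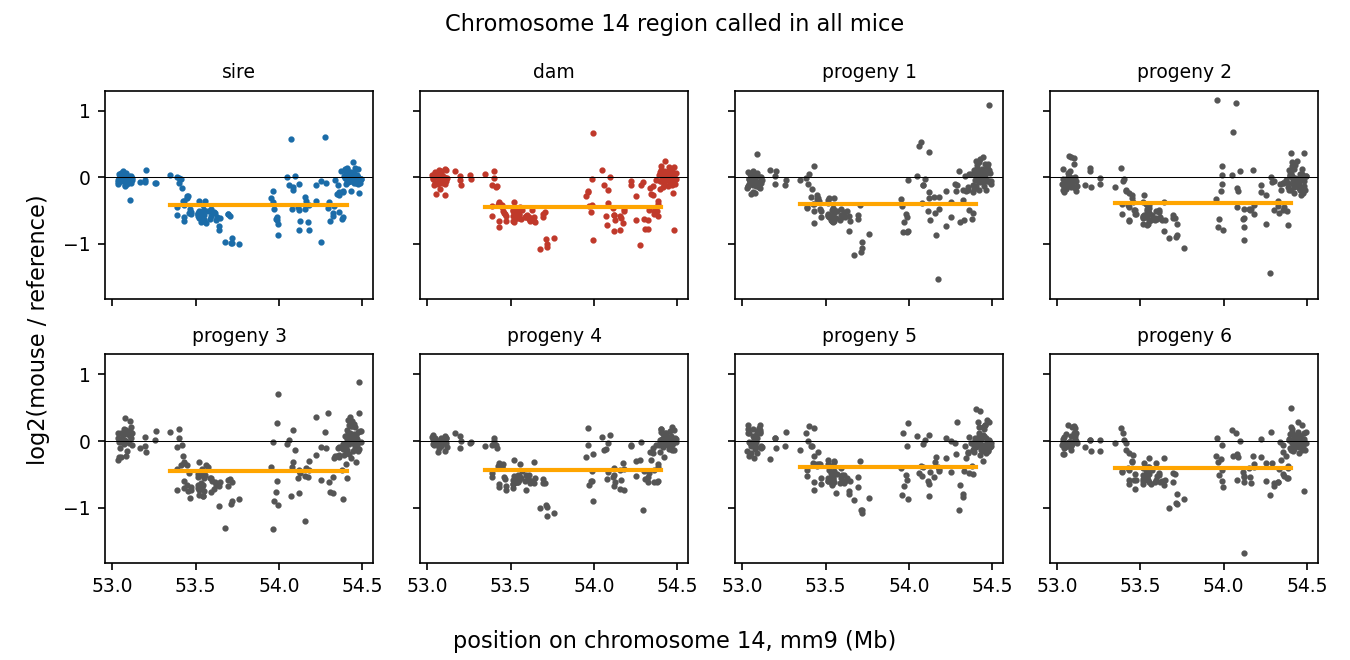
Log2 of mouse over reference (vertical axis) against position on chromosome 14 in Mb (horizontal axis) for each of the 8 mice. Each point is 1 probe, averaged over both dye orientations, with 40 probes on each side of the called region, and the orange line is the region mean drawn across the gap in probes. All region means lie between -0.45 and -0.38.

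Against the reference, the 6 progeny differed in the same parts of the genome. In limma, 21 of 94774 windows passed an adjusted p of 0.05, with 8 higher and 13 lower. Of these, 12 overlapped the chromosome 14 region, 8 the chromosome 4 region and 1 a region on chromosome 1. The chromosome 1 window had a progeny mean of -0.12, and 1 probe inside it had a progeny mean of -0.98. The 5 windows with the smallest adjusted p were all on chromosome 14. The window from 53543084 to 53585398 had a progeny mean of -0.53 ± 0.03 (SD, n = 6, limma adjusted p = 6.77e-13), and that from 53517370 to 53541248 had -0.55 ± 0.04 (limma adjusted p = 6.77e-13). The windows starting at 53590922, 53673489 and 53450514 had progeny means of -0.58, -0.68 and -0.52. All 6 progeny were lower in each of the 5 windows, which were chosen by the p-value of these same progeny. The sire and dam were also lower, at -0.56 and -0.55 in the window from 53543084. The progeny are siblings read against 1 reference mouse, so these p-values do not show a difference particular to the progeny. With scan day as a random block, a check added after the data were seen, 20 windows passed. With 1 dye orientation alone the count rose to 8235 with the mouse in Cy5 and 31438 with the mouse in Cy3.

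Several short autosomal regions were called in the dam and a part of the progeny and lay closer to the reference in the sire. On chromosome 3, from 25417435 to 25432738, 3 probes had means of -1.75 ± 0.10 in the dam, -1.59 ± 0.24 in progeny 3, -1.72 ± 0.07 in progeny 4 and -1.74 ± 0.01 in progeny 6, against 0.01 ± 0.02 in the sire. On chromosome 8, 43 probes from 102132083 to 102254870 were higher, with means of 0.26 in the dam and 0.27, 0.28 and 0.26 in progeny 3, 4 and 6. The same 4 mice were called lower on chromosome 5 from 123592752 to 123598838, with -0.72 in the dam, and on chromosome 11 from 112955152 to 112965298, with -0.41 in the dam. They were also called lower on chromosome 5 from 109215576 to 109223996, with -0.29 in the dam, a region outside the naming rule that was chosen after its values were seen. In this region and the one on chromosome 11, 1 of 5 probes passed 0.3 in the mouse with the largest mean. In the chromosome 5 region from 123592752, 1 of the 3 probes read -2.23 in progeny 3, and the other probes had a mean of -0.25. That probe read -2.06 in the dam, where the 3 probes on each side of it had a mean of -0.0081. In these 4 mice the median of the 68 probes on X lay between 0.92 and 0.98, and in the other 4 mice between -0.01 and 0.01. On Y the medians were -2.02 or lower in the first set and -0.16 or higher in the other. The values on X and Y are those of females against the reference male in the first set, and of males in the other. The regions called in these 4 mice therefore part the family by sex.

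**Figure D3:**
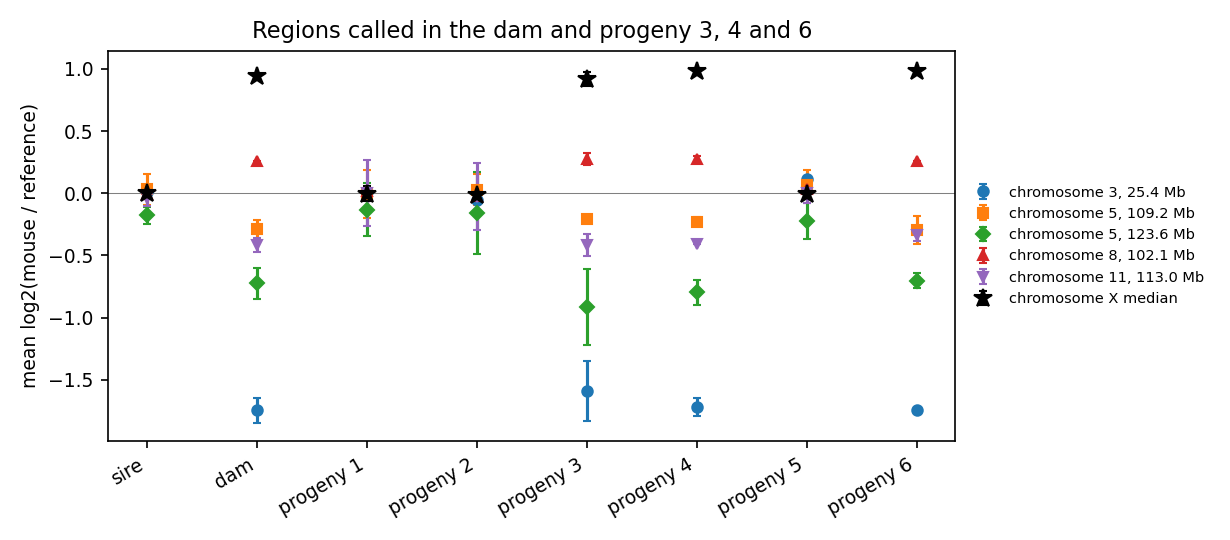
Mean log2 of mouse over reference (vertical axis) for the 5 regions called in the dam and progeny 3, 4 and 6, and the median of the X probes, in each of the 8 mice (horizontal axis). Error bars are the SD between the 2 dye orientations of a mouse. On chromosome 3 the called mice lie between -1.75 and -1.59 and the other mice between -0.05 and 0.12.

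The remaining named regions of a parent and some progeny were called in other sets of mice. On chromosome 1, from 153208318 to 153214999, the dam had a mean of -0.85 ± 0.21 and the progeny -0.20 ± 0.04 (SD, n = 6), and 1 of 5 probes carried the change. The mean of the dam was -0.20 with normexp and -0.0078 without dim probes, which leaves that probe out. A loss from 35857910 to 35865189 on chromosome 9 was called in the dam, with -0.67 ± 0.08, and in progeny 4 and 6, with -0.56 and -0.68. Progeny 3 had no call at -0.43 ± 0.16, and progeny 1, 2 and 5 read 0.06, 0.01 and 0.18. In progeny 6, 1 of the 3 probes of this region passed 0.3, and the other probes had a mean of 0.0002. On chromosome 14, from 61798066 to 61819370, 13 probes had a mean of -0.28 ± 0.07 in the dam and -0.27 ± 0.02 in progeny 4, both called, and of -0.18 and -0.21 in progeny 3 and 6 without a call, against -0.02, 0.04 and 0.05 in progeny 1, 2 and 5. In both of these regions progeny 3, 4 and 6 lay past the 99th percentile of random windows from the sire and not from the dam, so by value they parted the progeny like the regions above. A loss on chromosome 6 from 104236953 to 104242812 was called in the dam and progeny 4, with -0.29 ± 0.14 and -0.34 ± 0.10. Progeny 6 had no call there at -0.32 ± 0.21. In progeny 4, 1 of the 4 probes of this region passed 0.3, and the other probes had a mean of -0.047. A gain on chromosome 13 from 95703166 to 95710693 was called in the sire, with 0.43 ± 0.10, and in progeny 4, 5 and 6, with 0.32, 0.43 and 0.34, and 1 of its 4 probes passed 0.3 in the sire. A gain on chromosome 10 from 14582437 to 14593280 was called in the dam, with 0.42 ± 0.05, and in progeny 5, with 0.39 ± 0.11, while progeny 3 read -0.53 ± 0.05 on the same probes. The mean of the dam there fell to 0.046 with normexp and to 0.076 without dim probes. Of the 10 named regions of this class, 2 fell under an absolute mean of 0.25 with normexp. The whole class held 25 regions, and 56 with the shared dye effect removed from the calls as it was from the background search, which gave 5.

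Calls in progeny and in neither parent made up 211 regions. Of these, 117 also differed from both parents by more than random windows, 91 gains and 26 losses, and 94 did not pass this rule. The background search, from which the shared dye effect had been removed, gave 177 regions that passed it. With the dye effect removed from the calls as well, a setting added after the data were seen, 222 regions passed. Of the 117 regions, 107 had 3 or 4 probes, 113 were called in 1 mouse, and 49 had 1 probe past 0.3 in the mouse with the largest mean. Progeny 5 had 47 of them, progeny 1 and 2 had 21 each, progeny 6 had 20, progeny 3 had 8 and progeny 4 had 3. With the dye effect removed, progeny 1 to 6 had 40, 51, 14, 29, 65 and 34, and the background gave 65, 67, 11, 9, 12 and 15. The count was 5 with normexp background correction, and 69 without progeny replicate 5.

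The 10 named regions of this class were between 2.62 and 12.9 kb long, and 9 of them had 3 probes. The highest score belonged to a loss on chromosome 11 from 76357341 to 76361590 in progeny 4, at -0.60 ± 0.07, and progeny 6, at -0.57 ± 0.08. The same probes were called as a gain in progeny 5, at 0.93 ± 0.14, and read 0.55 ± 0.09 in progeny 3 and 0.34 ± 0.33 in the sire. In progeny 2 the losses on chromosome 17 from 88096979 to 88099826, chromosome 3 from 77204155 to 77207702 and chromosome 7 from 66244689 to 66257635 had means of -0.76 ± 0.12, -0.72 ± 0.45 and -0.70 ± 0.28. A gain in this mouse on chromosome 2 from 87123833 to 87129317 had a mean of 0.70 ± 0.34. Gains in progeny 1 lay on chromosome 17 from 28010642 to 28013263, with 0.82 ± 0.58, and on chromosome 7 from 77611524 to 77615982, with 0.53 ± 0.16, the latter also called in progeny 5, with 0.44 ± 0.10. In progeny 6 a gain on chromosome 14 from 51803173 to 51809460 had a mean of 0.62 ± 0.24, and a loss on chromosome 2 from 70082725 to 70085630 had a mean of -0.58 ± 0.41. Of the 10 regions, 7 had 1 probe past 0.3 in the mouse with the largest mean. With normexp, 9 of the 10 fell under an absolute mean of 0.25, the losses of progeny 4 on chromosome 11 to -0.026 and of progeny 2 on chromosome 17 to -0.057 among them, and the gain of progeny 1 on chromosome 17 stood at 0.25. Without dim probes, 6 of the 7 regions that kept probes fell under it.

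Regions called in a parent and in none of the progeny were short as well. There were 35 such regions, and 137 with the shared dye effect removed from the calls, against 75 in the background search with it removed. Of the 35, 31 had 1 probe past 0.3 in the mouse with the largest mean, as had 7 of the 10 named regions. The region with the highest score was a gain of 8 probes in the dam on chromosome 8 from 118282105 to 118295932, with a mean of 0.25 ± 0.03. Other gains in the dam lay on chromosome 7 from 47257189 to 47266937, chromosome 1 from 43389715 to 43396036 and chromosome 2 from 19170509 to 19178021, with means of 0.31, 0.27 and 0.29. The dam had a loss on chromosome 18 from 19066462 to 19073993, at -0.39 ± 0.12. In the sire, losses on chromosome 11 from 88120829 to 88125695, chromosome 10 from 22550543 to 22555560 and chromosome 3 from 135378985 to 135383715 had means of -0.40, -0.39 and -0.37. Gains in the sire on chromosome 3 from 129256890 to 129262606 and chromosome 19 from 37175762 to 37180063 had means of 0.35 and 0.40. Without a call, progeny 5 read 0.30 and 0.34 in the chromosome 1 and 2 gains of the dam and 0.45 and 0.64 in the chromosome 3 and 19 gains of the sire, and progeny 3 read -0.40 in the chromosome 3 loss, each past the parent. The absence of a call therefore does not show that the progeny lack these differences. With normexp, all 10 named regions of this class fell under an absolute mean of 0.25, and without dim probes 4 did.

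Window by window, the progeny as a group did not differ detectably from either parent. In limma, 0 windows passed for progeny against sire, 0 for progeny against dam and 0 for sire against dam. At an unadjusted p under 0.05 there were 935, 564 and 310 windows, which are 0.99, 0.60 and 0.33 percent of those tested. Each share lies far below what the threshold of 0.05 gives by chance, so these contrasts were conservative. The windows had an SD of 0.029 in the sire and 0.031 in the dam, and of 0.025 to 0.0545 in the progeny. In the chromosome 4 block, where sire and dam differed by 0.38 and the progeny lay at different levels, no window passed these contrasts. The absence of windows therefore does not show that progeny and parents are alike. With single probes, 7 probes passed for progeny against dam and 3 for sire against dam, all higher than in the dam. Progeny and parents were scanned on different days, so a shift between these groups and a shift between days cannot be told apart, while sire and dam shared 1 day.

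The number of called regions per mouse was 10 in the sire, 54 in the dam and 31, 36, 16, 25, 107 and 60 in progeny 1 to 6. The score is scaled by the noise of each mouse, which was 0.077 in both parents, 0.067 in progeny 4 and 0.16 in progeny 3. A short region thus needs a larger mean in a noisier mouse, and the counts rest on unlike limits of detection. The progeny mean was 45.8 ± 33.4 (SD, n = 6) and the mean of the 2 parents 32.0. The difference of 13.8 calls gave a two-sided exact permutation p of 0.643 over 28 splits, where 0.0357 is the smallest p this design allows. Background calls were 58 in the sire, 23 in the dam and 91, 86, 12, 20, 26 and 40 in the progeny, with the shared dye effect removed. Removed from the calls as well, it left 80 in the sire, 117 in the dam and 70, 94, 24, 65, 175 and 112 in the progeny, above background in every mouse but progeny 1. The difference reversed to -8.50 calls with the dye effect removed, a setting added after the data were seen, and to -1.50 calls with normexp background correction.

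**Figure D4:**
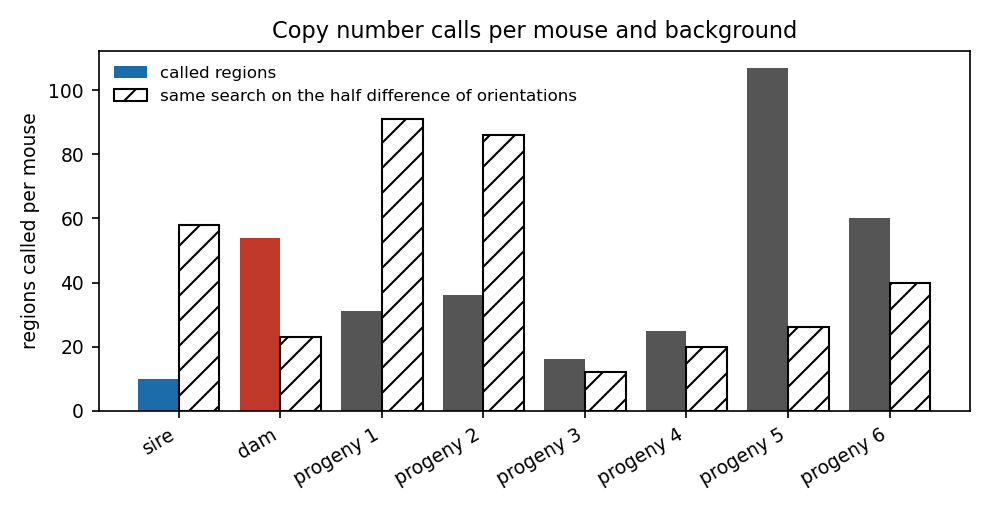
Number of regions called per mouse (vertical axis) in each of the 8 mice (horizontal axis). Filled bars are called regions, blue for the sire, red for the dam and grey for progeny, and hatched bars are calls of the same search on the difference of the dye orientations divided by 2, with the shared dye effect removed from the hatched bars only. Progeny 5 has 107 calls, and 26 in the background.

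Single probes at least 0.5 from 0 with the same sign in both orientations numbered 125 in the sire, 270 in the dam and 555, 693, 1282, 144, 2276 and 484 in progeny 1 to 6. Probes as far from 0 with opposite signs numbered 397, 130, 2409, 4031, 3707, 92, 556 and 514 in the same order of mice. Same-sign probes were more frequent than opposite-sign probes in the dam and progeny 4 and 5. The shared dye effect was not removed here. It moves the orientations in opposite directions, so the counts of same-sign and opposite-sign probes are not on a like footing. The means per mouse were 729 same-sign and 1479.5 opposite-sign probes, and at least 0.8 from 0 they were 91.5 and 74.5.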

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

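Of the tests in this part, those of probe signal and of a gain private to progeny 5 were chosen before their values were seen, and the others after, as was the use of the SE for the latter. Among 21 measures compared across the 6 progeny, 2 had a mouse far from the others, and chance alone gives about 1 in 20. Progeny 5 had 17 calls of at least 5 probes, and the Cy3 array of progeny 3 had 7688 spots not well above background.

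The probes on X and Y were outside the comparisons. The X medians were 0.94 in the dam, 0.92 in progeny 3, 0.98 in progeny 4 and 0.98 in progeny 6, above the 0.0052 of the sire. The Y medians were -2.02 in the dam, -3.23 in progeny 3, -2.24 in progeny 4 and -2.32 in progeny 6, against -0.02 in the sire.

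The 5 autosomal regions called together in the dam and progeny 3, 4 and 6 lie on 4 chromosomes. Scan day as the cause is argued against, since 2 of the mice with a call have a same-day partner without one. The X median separates the mice with a call from the others by 0.92, so probes that also bind sequence on X or Y are a candidate explanation. It was found and tested on the same mice, and the probe sequences were not aligned here. A loss passed on by the dam alone leaves the copy from the sire, so progeny would not fall below -1 where the sire reads near the reference. On chromosome 3, progeny 3, 4 and 6 had means of -1.59, -1.72 and -1.74, against 0.01 in the sire. Single probes in the chromosome 11 region and the chromosome 5 region from 123592752 read -1.99 or lower in these progeny, and -0.19 in the sire. For these regions the values argue against such a loss. Variants passed on by the dam stay open and untested for the remaining regions, because the regions were chosen for being called in the same mice.

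The gains called in progeny 5 numbered 103, with a mean log2 ratio of 0.51. A broad genomic wave as the whole cause is argued against by the 103 calls that progeny 5 had with a running median subtracted, more than any other mouse. The rank of progeny 5 did depend on other settings. It had 12 calls with a score of 8, below the 21 of progeny 4, the 18 of progeny 6, the 16 of the dam and the 13 of progeny 2. With normexp it had 21, where the dam and progeny 6 had 20 each. With the mouse in Cy3 only it had 88, below the 422 of progeny 3, the 182 of progeny 2 and the 90 each of progeny 4 and 6. With the mouse in Cy5 only it had the most, 189. Its calls numbered 64 without dim probes and 292 with a score of 5. Gains carried by progeny 5 alone as the whole cause were tested with the mouse of the highest mean among those scanned on other days. This was the dam, and the SE given for it does not allow for that choice. Over the same gains the dam had a mean of 0.12 ± 0.0135 (SE over the 103 gains, taken as independent), past the bound of 0.1 set in advance, and 86 of the gains lay above 0 in it. The margin is small, and the sire and progeny 1 to 4 had means of 0.019, 0.054, 0.032, -0.022 and 0.05. The 103 include the chromosome 4 block, at 0.95 in the dam, and gains called in the dam too, such as that on chromosome 10, at 0.42. The mean of the dam was not taken without them, so it does not decide whether the other gains belong to progeny 5 alone. Open explanations are weak probes, since the median signal of the probes in these gains lay at the 18.1 percentile of all probes, and an effect of DNA or hybridisation shared within the scan day, since progeny 6 had a mean of 0.16 there, with 96 gains above 0, above the other progeny on other days. Gains called in progeny 6 as well, such as that on chromosome 13 at 0.34, are among the 103 and raise its mean. Over all windows, progeny 5 and 6 had a Pearson correlation of 0.47. The other same-day pairs had 0.19 for sire and dam, 0.07 for progeny 1 and 2 and 0.16 for progeny 3 and 4. A shared scan day alone thus did not give a correlation of this size, and its cause was not tested. Real gains among the 103 stay possible, and these tests may miss single ones.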

How the results depend on the processing

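The removal of a shared dye effect, scan day as a block, the calls without each of the progeny and all checks of named regions were chosen after the data were seen; the other alternatives were planned. The number of regions called in all mice was 2 under each alternative run, with calls in the other 7 mice sufficing where 1 of the progeny was left out. The mean number of calls per mouse, 42.4, was 11.9 with normexp, 25.5 without dim probes, 72.8 with a score of 5, 13.1 with a score of 8, 27.5 with a mean of 0.4, 17.4 with at least 5 probes, 75.2 with Cy5 only, 127 with Cy3 only and 92.1 with the dye effect removed. The 117 regions of progeny and neither parent became 5, 43, 36 (score of 8), 49 (at least 5 probes), 256, 473 and 222 under the corresponding settings, and 69 to 118 without progeny replicate n. Removing progeny replicate 5 gave the 69. Calls per mouse without single progeny were 33.1 to 46.1. The difference between progeny and parents, 13.8 calls, reversed to -1.50 with normexp and to -8.50 with the dye effect removed. The 21 windows of progeny against reference became 153 with single probes, 39 with windows of 5 probes, 11 with windows of 20 probes, 8235 with Cy5 only and 31438 with Cy3 only, and were 20 to 25 without single progeny. With single probes, 7 passed for progeny against dam and 3 for sire against dam; with windows of 5 probes, 1 passed in each. No window passed for progeny against sire under any alternative run. Same-sign single probes per mouse, 729, were 5701 at 0.3, 91.5 at 0.8 and 207 with normexp; opposite-sign probes, 1479.5, were 74.5 at 0.8, where the balance turned. The chromosome 2 loss of progeny 6 from 70082725 reversed to 0.017 with normexp. Among 32 named regions, normexp moved 25 by more than the SD between orientations, and leaving out dim probes moved 12. Other window sizes change the number of windows tested, and a single orientation keeps the dye effect that the pair cancels; otherwise the cause was not tested. No paired analysis was possible because sire and dam are 1 mouse each. The GC correction and the gene lists were not run.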

Other observations

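A single probe on chromosome 1, from 153212126 to 153212185, had a log2 ratio of -4.24 ± 0.52 in the dam (SD between orientations), -0.02 ± 0.36 in the sire and -0.98 ± 0.17 in the progeny (SD, n = 6), with progeny values from -1.16 to -0.67. On 1 array of the dam this probe was not well above background, so its value in the dam is limited by the signal floor and shows a low signal rather than an exact ratio. The 3 probes on each side had means of 0.02 in the dam and 0.03 in the sire. It was 1 of 4 autosomal probes below -2 in both orientations of any mouse. The other 3, on chromosomes 3, 5 and 11, were below -1.99 in the dam and progeny 4 and 6 and at -2.10 or lower in progeny 3. These probes were chosen after their values were seen.

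All tests of the chromosome 4 block were chosen after its levels were seen. A difference carried by the reference mouse alone is argued against as the whole cause by the 0.38 between dam and sire, and a dye effect by the largest SD between orientations of a mouse, 0.0445. All 6 progeny lay within the range of a parent, 3 at the level of the sire and 3 at that of the dam, which is consistent with levels inherited from the parents. The array gives ratios and no absolute copy number.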
